A study of Mus musculus with 8 samples.

How the data were processed

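Serum exosomes were enriched with ExoQuick, RNA was extracted with a SeraMir kit, and libraries were made with a stranded SMARTer pico-input total RNA kit, per the labels' protocols. The submitters' processing notes name FastQC 0.11.5, Trimmomatic 0.33.0 and kallisto 0.43.0 and the builds GRCm38.p5 and CanFam3.1. The index, the annotation release and the filters are not given in the sources used here. The deposited table holds 1 value per gene and library for mouse and canine genes together, and all values are whole numbers. Although the table calls them counts, they are treated as a score: the deposited score of each library sums to nearly the same total (977106 to 989183) whatever its content, and it does not rise with transcript length, as raw counts would. The values behave as TPM over both species, made whole. Whether they were rounded or shortened was not settled. Such values keep no depth, so no count interval or floor is given, and a 0 is reported only as listed at 0.

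A count test had been planned before the data were examined. Because the values are not counts, it was replaced by limma (3.58.1, in R 4.3.3) on log2(scaled value + 1). Genes with a value of at least 10 in at least 2 libraries were kept, which left 7655 mouse and 217 canine genes. Libraries were scaled by a trimmed mean of log ratios to the first week 0 library, without weights, trimming 30% of the ratios and 5% of the levels at each end. All 8 libraries entered 1 fit with a mean per group, so that they share 1 estimate of the spread (4 residual degrees of freedom), and the moderated variance followed a trend on the level. Adjusted p-values are Benjamini-Hochberg values within each of 5 comparisons: OSCA-32 against PBS, OSCA-40 against PBS, the mean of both lines against PBS, PBS at week 8 against week 0, and OSCA-40 against OSCA-32.

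Before the data were examined, 29 gene lists were fixed: vesicle components, erythroid cells, platelets and megakaryocytes, neutrophils, monocytes and macrophages, B cells and plasma cells, T and NK cells, hepatocytes, osteoblasts and bone matrix, osteoclasts, skeletal muscle, endothelial cells, fibroblasts, adipocytes, acute phase, interferon-stimulated genes, inflammatory cytokines, cell cycle, hypoxia and glycolysis, unfolded protein response, mitochondrially encoded mRNAs, nuclear oxidative phosphorylation, cytosolic ribosomal proteins, histones, structural RNAs, brain, lung epithelium, signature genes recalled from earlier work and osteosarcoma-linked genes. The 23 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Neutrophils, monocytes and macrophages, inflammatory cytokines, structural RNAs, lung epithelium and the recalled signature had fewer tested genes, and none of their members was called in any of the 5 comparisons. The rule for named genes was fixed at the same time: per comparison, up to 10 genes higher and 10 lower with the largest fold change among those that passed, with an established symbol and with every library of one side above every library of the other; where fewer than 5 qualified in a direction, the genes with the smallest p that met the other conditions; the 3 members with the smallest p of each list that passed or held a called gene; and the 10 genes with the highest mean. Of the genes the rule selected, those that passed are given, with some of the list members that did not. 1 list member is not reported here. The canine share was compared by an exact permutation test over all 70 splits (SciPy 1.17.1). Its difference is the value reported, and no interval is given because the depth is unknown.

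Gene symbols and coordinates come from GENCODE mouse release 21 on GRCm38, which matched 31171 of the 31300 mouse identifiers; none of the 20716 canine identifiers has a name in the tables used here. The mitochondrial mRNAs were compared with all listed mouse transcripts by BLAST 2.17.0. At 99% identity or more over 200 bases or more, 7 of them had a copy on chromosome 1, between 24611535 and 24616197.

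The procedure was tested on simulated data with 200 genes changed by a known amount among 7872. For OSCA-40 against PBS it recovered 21 of 100 genes changed 2-fold and 59 of 100 changed 4-fold, with 2 other genes called; for OSCA-32 against PBS it recovered 27 and 70, with 5 others; for both lines against PBS 34 and 66, with 6 others; for PBS against week 0 25 and 73, with 4 others; and for OSCA-40 against OSCA-32 20 and 68, with 3 others. Changes of 2-fold were therefore mostly missed.

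Alternatives fixed beforehand were median-of-ratios scaling, library totals alone, no filter, a mean of at least 50, only the groups compared, the replicate number as a block, removal of mitochondrial, haemoglobin and structural RNA genes, leaving out each library, week 0 as the reference, and other list tests. Chosen after seeing the data were pseudocounts of 0.25 and 4, a minimum of 5, no variance trend, mouse genes alone, summed mitochondrial copies, a PBS library of its own for each line, and the canine share without its highest pair of genes. A chi-square test of identity between replicates was planned and is void without counts; the replicates of each group had Spearman correlations across genes of 0.770 to 0.819.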

Results

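RNA carried by serum exosomes, the small membrane vesicles that cells shed into blood, was sequenced from immunodeficient NCr nu/nu mice. The mice received an injection of 10 µl into the tibia, either of phosphate-buffered saline (PBS) or of 100000 cells of OSCA-32 or OSCA-40, which are cell lines of osteosarcoma, a bone cancer, from dogs. Serum was pooled, and the 8 libraries fall into 4 groups of 2: serum taken before injection (week 0), and serum taken at week 8 from mice given PBS, OSCA-32 or OSCA-40. Nothing in the labels says that the 2 libraries of a group come from separate animals, so p-values measure only the spread between these libraries, which may be technical. The deposited table lists 52016 genes, 31300 of mouse and 20716 of dog. Each library sums to between 977106 and 989183, so the values are relative amounts within a library and the sequencing depth behind them is unknown. The series title names the search for an exosomal gene signature of canine osteosarcoma, and the table lists canine genes apart from mouse genes. Because canine genes also held values in mice without canine cells, a gene listed as canine or as mouse is not shown to come from the graft or the host.

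The canine share of each library came first. Canine genes held 16.7% ± 0.910 (SD, n = 2) of the library total at week 0 and 14.99% ± 0.363 (SD, n = 2) in PBS mice, which carried no canine cells. The share was 44.0% ± 1.03 (SD, n = 2) with OSCA-32 and 69.6% ± 1.62 (SD, n = 2) with OSCA-40. The 4 tumour libraries exceeded the 4 tumour-free libraries by 40.9 percentage points, with p = 0.0286 in an exact two-sided permutation test, the smallest p that the 70 splits allow. Each library counts as a separate unit in this test, though those of a group may be repeats of the same pooled serum. Most of the 40.9 points lay in a pair of canine genes, which held 45.2% of the tumour libraries and 5.41% of the tumour-free libraries on average. ENSCAFG00000030616 was listed at 0 in the 4 tumour-free libraries and at 564602 and 582489 in the OSCA-40 libraries. ENSCAFG00000031490 was already listed at 42333 to 63599 in the tumour-free libraries, stood at 324687 and 311612 with OSCA-32, and was listed at 8 in both OSCA-40 libraries. With this pair taken out of the canine values and of the library total, the canine share was 22.4% ± 6.10 (SD, n = 4) in tumour libraries. It was 11.1% ± 0.394 (SD, n = 4) in tumour-free libraries, with p = 0.0286 in the same exact permutation test. Removal from the total raises the share of the other canine genes most where the pair was largest.

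**Figure D1:**
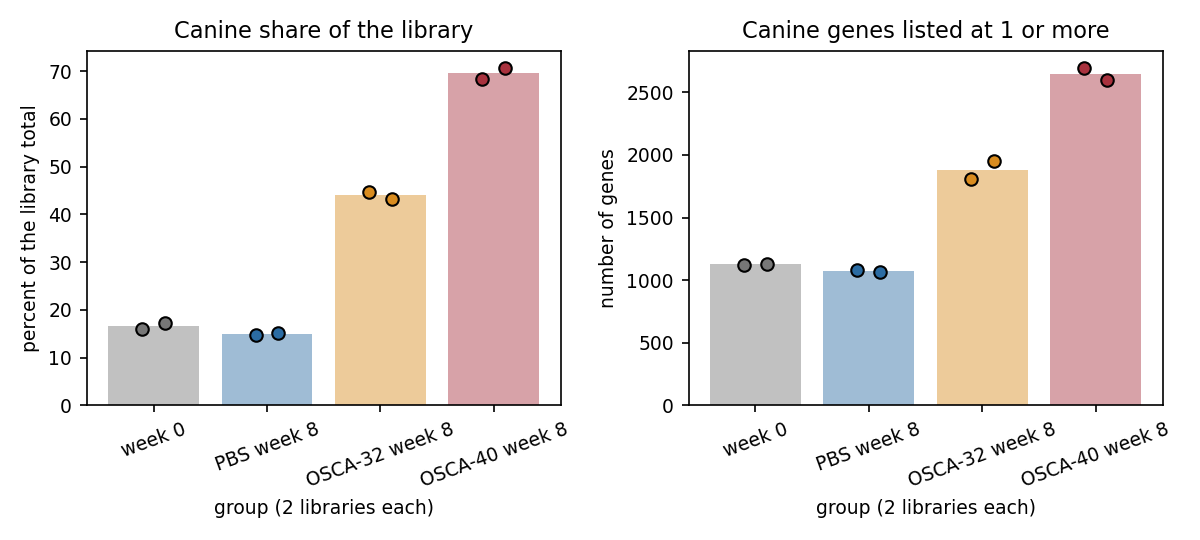
Canine share of each library in percent of its total (left) and number of canine genes listed at 1 or more (right), by group; bars are means of 2 libraries and points are the libraries. The 4 tumour libraries lie between 43.3% and 70.7%, and the 4 tumour-free libraries between 14.7% and 17.4%.

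More canine genes were also seen in the tumour groups. Between 1068 and 1131 canine genes were listed at 1 or more in each tumour-free library, against 1807 and 1952 with OSCA-32 and 2697 and 2597 with OSCA-40 (exact two-sided permutation test, 4 against 4 libraries, p = 0.0286). Of the canine genes at 0 in all 4 tumour-free libraries, 314 were at 1 or more in all 4 tumour libraries, whereas 13 showed the opposite arrangement. The number of canine genes at 10 or more did not separate the 4 tumour from the 4 tumour-free libraries (163 against 153 on average, exact permutation p = 0.314). By line it was 152 and 151 with OSCA-32 and 185 and 165 with OSCA-40, against 147 to 158 in the tumour-free libraries. The sources used here do not pair canine identifiers with gene names, so canine genes are reported as counts.

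Because canine genes took a larger part of the tumour libraries, the mouse genes as a whole were lower there. As deposited, the median mouse gene among those tested differed from PBS by -0.56 on the log2 scale with OSCA-32 and by -1.53 with OSCA-40, and PBS differed from week 0 by 0.05. Values were therefore scaled on the bulk of the genes, and every fold change below is relative to that shift, on the log2(scaled value + 1) scale, which understates the change of low genes. With scaling, 55.6% of the mouse genes called in OSCA-40 were higher, and with library totals alone 0.229% were. The corresponding shares were 69.0% and 1.71% for OSCA-32, 65.7% and 0.375% for both lines together, and 45.7% and 0.309% for OSCA-40 against OSCA-32. The larger direction also turned under other settings: the share for OSCA-40 was 41.9% or 42.5% without its first or second library, and for OSCA-32 without its first library 6 mouse genes were higher and 9 lower. Among genes with a mean of at least 50 the shares were 41.7% for OSCA-40, 39.8% for OSCA-32 and 42.0% for both lines. Between the lines 36 were higher and 24 lower without the first OSCA-32 library, 22 and 11 without the second, and 11 and 8 with only these groups fitted. Of the 222 mouse genes called higher with OSCA-40, 47 were higher as deposited, and all 177 called lower were lower as deposited. Of the genes called higher, 21 of 29 were higher as deposited for OSCA-32 and 45 of 159 for both lines. Between the lines it was 25 of 64.

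The comparison of OSCA-32 with PBS asked what changed in serum exosomes of mice carrying that line. Of 13 mitochondrially encoded mRNAs, 6 rose, and 13 mouse genes fell. Of the 6 tested genes of the platelet list only Tmsb4x passed as higher. The mitochondrial list passed camera, with an adjusted p = 0.171 with an estimated correlation, and mt-Co3 and mt-Nd4l, at -1.29 ± 1.57 and -2.86 ± 2.19, did not pass. Summed with their nuclear copies both took the opposite sign: mt-Co3 passed at 1.37 ± 0.20, and mt-Nd4l, at 0.73 ± 0.23, did not. Of the 19 named genes called here, Ccdc107, Cd300lf, Ndufb2, Rdh16f1 and Wapl passed without each of the 8 libraries; Tmsb4x did not pass without either PBS library, nor any of the 6 mitochondrial mRNAs without the second PBS or the first OSCA-32 library, all with the same sign. mt-Nd6, mt-Nd2, mt-Nd5, mt-Nd4 and mt-Cytb, which encode subunits of respiratory chain complexes, rose by log2 fold changes of 1.34 to 1.87, with mt-Nd4 (mitochondrial genome, 10167 to 11544) at 1.50 ± 0.15 (SE), and mt-Co1 rose by 0.98 ± 0.12. Tmsb4x (X, 167207093 to 167209315), an actin-binding peptide abundant in platelets, rose by 1.36 ± 0.14. Cd300lf, an inhibitory receptor of myeloid cells (11, 115116214 to 115133992), fell by 3.13 on the log2 scale, from 122 and 124 in PBS to 8 and 9. Ndufb2, a nuclear-encoded complex I subunit (6, 39592574 to 39603382), fell by 2.20, from 468 and 541 to 74 and 71. In tumour-free libraries the median gene of the nuclear oxidative phosphorylation list stood at 7.75 and of the monocyte and macrophage list at 4.875. The former list did not pass (camera adjusted p = 0.757), and the latter had too few genes to be tested. Whether the values listed for Cd300lf and Ndufb2 come from their mRNA was not tested.

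In the limma fit, 86 of 7872 genes passed an adjusted p of 0.05: 29 mouse genes higher and 13 lower, 42 canine genes higher and 2 lower. With library totals alone, 44 canine genes were called higher and 23 lower. Rdh16f1, of the retinol dehydrogenase family, was listed at 0 in the 4 tumour-free libraries and at 19 and 26 with OSCA-32 (adjusted p = 0.0016, limma). It was 1 of 7 mouse genes, among 1493 at 0 in the tumour-free libraries, that were at 1 or more in all 4 tumour libraries, and whether canine reads were assigned to such genes was not tested. Ccdc107 rose by 2.06 ± 0.18 and Ttyh1, a chloride channel, by 1.28 ± 0.16. Among the genes that fell were Wapl, which releases cohesin from chromosomes, at -1.13 ± 0.11, Alpk2 at -1.03 ± 0.12, the collagen receptor Ddr2 at -0.93 ± 0.11, Focad at -0.89 ± 0.10, Fam81a at -0.79 ± 0.09, Nlrp9b at -0.79 ± 0.13 and the latent TGF-beta binding protein Ltbp1 at -0.45 ± 0.07. In PBS Wapl stood at 1179 and 1112, Focad at 967 and 982 and Ltbp1 at 1010 and 946. The median ribosomal protein gene stood at 9 and 10 there. Whether such high values come from the mRNA of these genes was not tested. Among the mitochondrially encoded mRNAs none passed as lower, 8 rose adjusted over the list alone, and the adjusted p of camera was 1.19e-07. Of 6 platelet and megakaryocyte genes, 1 rose (3 adjusted over the list alone), and the list passed with an adjusted p of 0.0031; its adjusted p = 0.233 with an estimated correlation. The platelet chemokines Pf4 and Ppbp had log2 fold changes of 0.98 ± 0.25 and 1.03 ± 0.27 that did not pass. The other 21 lists did not pass (lowest adjusted p = 0.183). Fitting only the 4 libraries compared gave 46 genes, and the count was 42 or 36 without the first or second PBS library and 44 without the first OSCA-32 library.

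The comparison of OSCA-40 with PBS asked the same of the other line. Single transcripts known from platelets, red cells, liver and the mitochondrion rose relative to the bulk of mouse genes, and the tetraspanin Cd9 fell. Of the corresponding lists the platelet, erythroid and mitochondrial ones passed camera, each with an adjusted p = 0.421 or more with an estimated correlation, and the hepatocyte list did not pass. Of the 34 named genes called here, 17 passed without each of the 8 libraries, among them Pf4, Tmsb4x, Hba-a2, Apoe and Cd9, whereas Ppbp, Fabp1, Saa2 and Alb each lost the call without at least 1 library. Pf4 (5, 90772435 to 90773383) rose by 2.76 ± 0.25 (SE), Tmsb4x by 2.71 ± 0.14 and Ppbp by 1.57 ± 0.27. Hba-a2, an alpha-globin gene (11, 32296489 to 32297298), rose by 1.70 ± 0.07, while its deposited values were 184 and 189 in PBS and 194 and 196 with OSCA-40. Among liver products, the fatty acid carrier Fabp1 rose by 2.91 ± 0.55, Apoe (7, 19696109 to 19699188) by 2.40 ± 0.29, the acute-phase protein Saa2 by 1.98 ± 0.31 and albumin, Alb, by 1.70 ± 0.30. Of these genes, grouped after they were called, only Alb is on the hepatocyte list. Saa2 is on the acute phase list, which did not pass (camera adjusted p = 0.338). As deposited, Ppbp was 7 and 9 in PBS and 9 and 8 with OSCA-40, and Alb was 7 and 13, and 11 and 11. The rises of Ppbp and Alb, like that of Hba-a2, therefore rest largely on the scaling. For Pf4, Tmsb4x, Fabp1, Apoe and Saa2 both OSCA-40 libraries were above both PBS libraries as deposited. Saa2 was 7 and 10, and 11 and 13, where the median protein-coding gene stood at 5 in PBS. Cd9 (6, 125460266 to 125494791) fell by 1.20 on the log2 scale. In the tumour-free libraries Cd9 stood at 192 to 234, and the median gene of the vesicle list at 7.875. Whether the values listed for Cd9, here and in the comparisons below, come from its mRNA was not tested.

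Here 531 genes passed: 222 mouse genes higher and 177 lower, 125 canine genes higher and 7 lower. The canine split depends on the scaling: with library totals alone, 77 canine genes were called higher and 95 lower. Rdh16f1 and Trim5, a restriction factor gene (7, 104263386 to 104288094), were listed at 0 in every tumour-free library and at 21 and 20, and at 7 and 6, with OSCA-40. Ccdc107 rose by 2.49 ± 0.18, the histone gene Hist2h2aa1 by 2.60 ± 0.42, Vps33a, of lysosomal trafficking, by 2.09 ± 0.23, and B2m, the light chain of MHC class I, by 2.06 ± 0.24. Cd300lf changed by -3.15 ± 0.12 and Ndufb2 by -2.36 ± 0.11. Piga, Speer4c, Defa25, Defb45, Vcan and Trav6-5 passed as lower and were listed at 0 in both OSCA-40 libraries; in PBS the proteoglycan gene Vcan stood at 11 and 8. Polr3g changed by -3.11 ± 0.66 and Phf6 by -2.77 ± 0.57, and with OSCA-40 they were listed at 1 and 0, and at 2 and 8. Several of these are members of families of close copies (Hba-a2, Hist2h2aa1, Saa2, Defa25, Speer4c), whose reads can be split between copies, so their values are uncertain.

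By list, 3 of 6 platelet genes rose (4 adjusted over the list alone; camera adjusted p = 0.0027, and adjusted p = 0.421 with an estimated correlation). Of 11 erythroid genes, 1 rose, Hba-a2 (1 adjusted over the list alone; camera adjusted p = 0.0027, and adjusted p = 0.496 with an estimated correlation); Ank1 at 0.95 ± 0.31 and Hbb-bs at 0.49 ± 0.17 did not pass. Of 13 mitochondrially encoded mRNAs, 5 rose, among them mt-Nd4 at 1.45 ± 0.15 and mt-Nd6 at 1.78 ± 0.29, and 1, mt-Co2, passed as lower at -1.91 ± 0.31 (the same numbers adjusted over the list alone; camera adjusted p = 0.0342, and adjusted p = 0.496 with an estimated correlation). Summed with its identical nuclear copy, mt-Co2 took the opposite sign, at 1.25 ± 0.16 (adjusted p = 0.0037, limma). mt-Co3 and mt-Nd4l had values of -1.54 ± 1.57 and -3.37 ± 2.19 alone and of 0.67 ± 0.20 and 0.71 ± 0.23 summed, none of which passed. The hepatocyte list did not pass (adjusted p = 0.109), with 2 of 8 genes higher, Alb and the iron carrier Trf at 0.76 ± 0.17 (2 adjusted over the list alone). Cd9 was the 1 of 13 vesicle components that passed (1 adjusted over the list alone); 7 of the 13 had a positive fold change, and the list did not pass (adjusted p = 0.738, median 0.06, mean -0.19, direction of the test lower). Single members passed in other lists that did not. Clcn7, on the osteoclast list, rose by 0.77 ± 0.10, the endothelial adhesion molecule Pecam1 by 1.28 ± 0.15 and the interferon-induced Xaf1 by 1.17 ± 0.26. Rpl36 changed by -1.60 ± 0.23 and the p53 regulator Mdm2 by -1.31 ± 0.28. As deposited, Clcn7 was 435 and 438 in PBS and 221 and 256 with OSCA-40. The median gene of the osteoclast list stood at 5.375 in tumour-free libraries, and whether the values of Clcn7 come from its mRNA was not tested. With OSCA-40, Rpl36 was listed at only 3 and 2 and Mdm2 at 1 and 1. In the endothelial list 1 gene was higher and 1 lower adjusted over the list alone, and Flt1, at -0.94 ± 0.23, did not pass over all genes; in the interferon list 2 were higher adjusted over the list alone, and Mx2, at -1.03 ± 0.33, did not pass. With library totals alone Clcn7, Trf, Pecam1, Xaf1, mt-Nd4 and mt-Cytb took the opposite sign. Fitting only the 4 libraries compared gave 320 genes, and leaving out the first or second PBS library gave 268 or 297; without a trend of the variance on the level the count was 313.

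**Figure D2:**
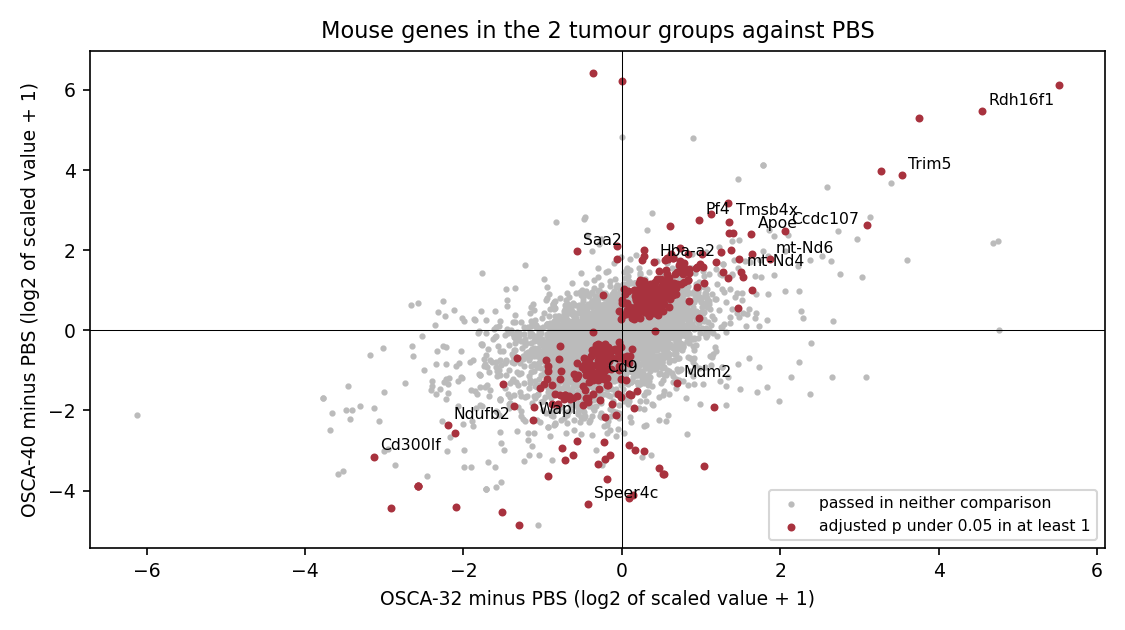
Log2 fold change of each tested mouse gene in OSCA-32 (x axis) and OSCA-40 (y axis) against the same 2 PBS libraries, on the log2(scaled value + 1) scale; red points passed in at least 1 comparison. Cd300lf lies at -3.13 and -3.15, and Tmsb4x at 1.36 and 2.71.

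Averaged over both lines, 353 genes differed from PBS: 159 mouse genes higher and 83 lower, 107 canine genes higher and 4 lower. With library totals alone, 73 canine genes were called higher and 86 lower. Tmsb4x rose by 2.03 ± 0.12 (SE), Apoe by 2.02 ± 0.25, Pf4 by 1.87 ± 0.22, Alb by 1.44 ± 0.26 and mt-Nd6 by 1.82 ± 0.25, and the defensin gene Defb35 by 1.65 ± 0.35. Rdh16f1 and Trim5, at 0 in the tumour-free libraries, passed as higher. Ccdc107 rose by 2.28 ± 0.15, mt-Nd4 by 1.47 ± 0.13, mt-Nd2 by 1.33 ± 0.17, mt-Cytb by 1.33 ± 0.14, Ppbp by 1.30 ± 0.23, Pecam1 by 0.86 ± 0.13 and Clcn7 by 0.62 ± 0.09. Cd300lf changed by -3.14 ± 0.11, Ndufb2 by -2.28 ± 0.09, Wapl by -1.68 ± 0.09, Prr14l by -1.60 ± 0.30, Synpo by -1.51 ± 0.30, Arfgap2 by -1.42 ± 0.24, Alpk2 by -1.24 ± 0.10, Yipf3 by -1.19 ± 0.18, Paip2 by -1.18 ± 0.13, Focad by -1.12 ± 0.09 and Cd9 by -0.73 ± 0.09. Cd9 was not called for OSCA-32 alone: its scaled means were 135 in PBS, 112 with OSCA-32 and 58.0 with OSCA-40. The list members Pf4, Ppbp, Alb, Hba-a2, Pecam1 and Clcn7 were also not called for OSCA-32 alone. Scaled means of Hba-a2 were 214 at week 0, 126 in PBS, 166 with OSCA-32 and 412 with OSCA-40. Prr14l and Synpo were listed at 1 to 7 in the tumour libraries. The erythroid, platelet and mitochondrial lists passed camera, with adjusted p of 0.0066, 0.0008 and 0.0003 and 1 of 11, 3 of 6 and 6 of 13 members higher (the same numbers adjusted over each list alone). The adjusted p = 0.440 with an estimated correlation for the erythroid list, and adjusted p = 0.236 with an estimated correlation for the platelet and the mitochondrial list. Hba-a2, at 1.05 ± 0.06, Pecam1 and Clcn7 took the opposite sign with library totals alone. Of the 27 named genes called, 13 passed without each of the 8 libraries, among them Tmsb4x, Pf4, Hba-a2, Cd300lf and Ndufb2, whereas Apoe and mt-Nd6 did not pass without the first PBS library, nor Alb without any single library but the second PBS one. Without the first or second PBS library the count was 135 or 163, and without the variance trend it was 204.

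Both lines shared 26 mouse genes called higher and 10 called lower, where independent lists of these sizes would share 0.841 and 0.301. Across mouse genes, which are not independent replicates, the log2 fold changes of the lines correlated with r = 0.501. In 100 simulations of unchanged groups against the same PBS libraries the mean was 0.503. The correlation cannot decide whether the lines agree beyond their shared controls. Changes particular to either line lower r, and the simulation gave every library the same spread. The covariance was 0.217 against a simulated 0.109, a difference of 0.108. In the simulations no gene was called in both. With no library in common, OSCA-32 against PBS and OSCA-40 against week 0 gave r = 0.262 and a covariance of 0.109. OSCA-32 against week 0 and OSCA-40 against PBS gave r = 0.217 and a covariance of 0.0925. The PBS libraries were also split, 1 to each line, with the lone libraries assumed to vary like the others. In the 2 orders r was 0.239 and 0.217 and the covariance 0.126 and 0.116. The lines then shared 4 and 5 mouse genes called higher, where independent lists would share 0.0470 and 0.117, and in both orders 4 called lower, where independent lists would share 0.0287 and 0.0329. Part of the larger overlap against the same PBS libraries may come from the shared controls.

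The tumour-free groups differed in few genes. From week 0 to PBS at week 8, 3 of 13 mitochondrially encoded mRNAs rose and Hba-a2 fell, with 13 of 7872 genes past the threshold: 4 mouse genes higher and 5 lower, 1 canine gene higher and 3 lower. mt-Co1 rose by 1.50 ± 0.12 (SE) and mt-Cytb by 1.38 ± 0.17. mt-Co2 passed at 3.76 ± 0.31, but a nuclear copy of it is 100% identical over 681 bases; summed with that copy it changed by 1.24 ± 0.16. All 13 mitochondrially encoded mRNAs had a positive fold change, 3 passed over all genes and 9 adjusted over the list alone, and the list passed camera with an adjusted p of 2.73e-20 and, with an estimated correlation, adjusted p = 0.0275. Hba-a2 fell by 0.76 on the log2 scale, and the erythroid list did not pass (adjusted p = 0.0507). Rhox8 (X, 37874778 to 37878944) and Stra8 (6, 34920163 to 34939344), known from the germ line, fell by 1.44 and 1.25, and Foxp2 fell by 0.53. At week 0 Foxp2 stood at 1069 and 1081, and whether values that high come from its mRNA was not tested. Values that did not pass were mt-Nd1 at 1.46 ± 0.21, Zfp697 at 0.42 ± 0.06 and Ovgp1 at -0.57 ± 0.08. Injection and 8 weeks of time differ together here. Leaving out any 1 of the 8 libraries gave 2 to 7 genes. Fitting only these 4 libraries, or leaving out either week 0 library or the first PBS library, gave 2 genes, both canine, and 4 genes passed without the second PBS library. In each of these 5 fits mt-Co1, mt-Cytb, mt-Co2, Hba-a2, Rhox8, Stra8 and Foxp2 kept their sign and did not pass.

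The lines also differed from each other in genes listed as mouse. Against OSCA-32, and relative to the bulk of genes, OSCA-40 had higher Saa2 (2.55 ± 0.31, SE), Vps33a (2.15 ± 0.23), Pf4 (1.78 ± 0.25), Tmsb4x (1.35 ± 0.14) and Hba-a2 (1.30 ± 0.07). Lower were Cd9 (-0.94 ± 0.11), Mdm2 (-2.02 ± 0.28) and mt-Nd1 (-1.14 ± 0.21). As deposited, Tmsb4x was 85 and 65 with OSCA-32 and 95 and 88 with OSCA-40. Hba-a2 was 157 and 173, and 194 and 196. Mdm2 was listed at 12 and 11 with OSCA-32 and at 1 and 1 with OSCA-40. Of the 25 named genes called here, only Hba-a2, Tmsb4x and Vps33a passed without each of the 8 libraries: Saa2 did not pass without the second OSCA-40 library, Cd9 without the second OSCA-32 library, Mdm2 without either OSCA-32 library, Pf4 without each single tumour library and mt-Nd1 without each of the 8. In all 217 genes passed: 64 mouse genes higher and 76 lower, 75 canine genes higher and 2 lower. With library totals alone, 41 canine genes were called higher and 67 lower. The immunoglobulin segment Ighv1-12 rose by 2.77 ± 0.43, the laminin receptor Bcam by 2.09 ± 0.35, H2-T24 by 1.83 ± 0.28, the splicing factors Rbm17 and U2af2 by 1.59 ± 0.27 and 1.34 ± 0.26, and Phkg2 by 1.49 ± 0.17. Zfp991 changed by -2.10 ± 0.33, the carnitine acetyltransferase gene Crat by -1.95 ± 0.28, the kinase gene Pdpk1 by -1.70 ± 0.30, Zdhhc9 by -1.67 ± 0.26, Pramel5 by -1.64 ± 0.22 and Rpl36 by -1.55 ± 0.23, and Speer4c and Vcan passed as lower and were listed at 0 in both OSCA-40 libraries. In these libraries Crat was listed at 1 and 1, Pdpk1 at 2 and 1, Zdhhc9 at 2 and 3 and Rpl36 at 3 and 2. These falls, like that of Mdm2, rest on the lowest whole numbers. The platelet list (2 of 6 higher) and the erythroid list (1 of 11 higher) passed camera, each with an adjusted p of 0.0380, and 2 members rose in each adjusted over the list alone; adjusted p = 0.673 with an estimated correlation for both. mt-Co2 at -3.07 ± 0.31 and mt-Co1 at -0.67 ± 0.12 passed when taken alone, and summed with their nuclear copies they changed by 0.10 ± 0.16 and 0.04 ± 0.15. Pecam1, at 0.83 ± 0.15, took the opposite sign with library totals alone. Leaving out 1 library gave 69 to 166 genes, and fitting only these 4 libraries gave 84.

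**Figure D3:**
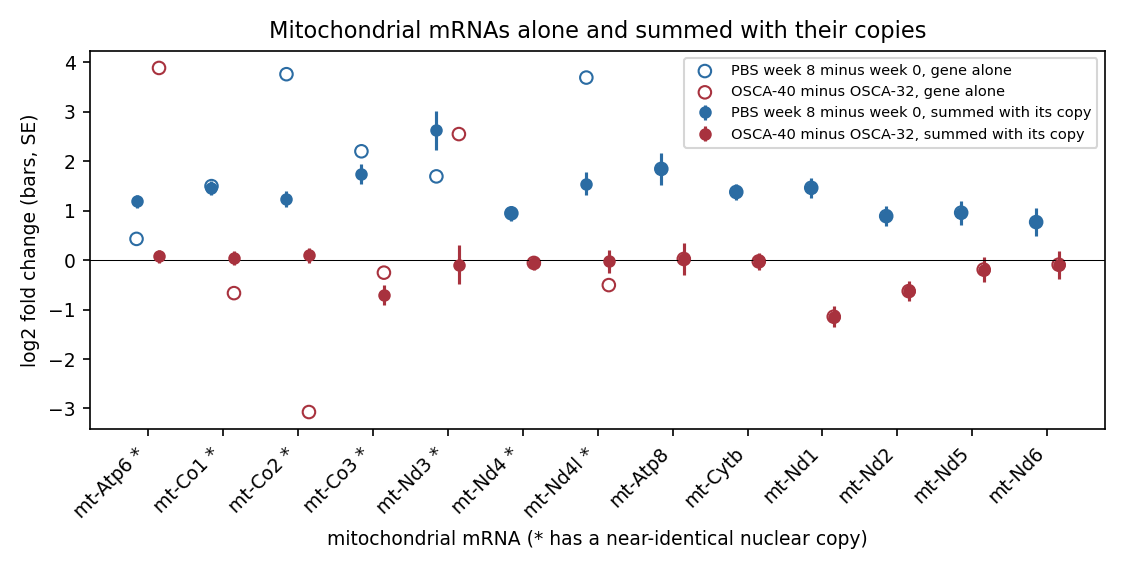
Log2 fold change of each mitochondrially encoded mRNA taken alone (open points) and summed with its near-identical copy on chromosome 1 (filled points, bars are SE), for PBS week 8 minus week 0 and for OSCA-40 minus OSCA-32. Summed, mt-Co2 moves from 3.76 to 1.24 in the first comparison and from -3.07 to 0.10 in the second.

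Among the 10 genes with the highest mean value were 4 canine genes and the mouse genes Gm10800, Gm10801, Gm10719, Gm10718, Gm29013 and Gm42857. Gm10800 (2, 98666547 to 98667301) averaged 164668 at week 0, 161436 in PBS, 102956 with OSCA-32 and 60610 with OSCA-40, and the canine gene ENSCAFG00000031885 averaged 46252 in PBS and 16170 with OSCA-40. The canine gene ENSCAFG00000032276 averaged 9319.5 in PBS, 20313 with OSCA-32 and 24373 with OSCA-40.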

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

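All tests of explanations in this part were chosen after the results were seen. The results below were listed because the tumour lines differed in the direct comparison of OSCA-40 with OSCA-32, from the same fit. In mouse and canine genes together 217 genes differed between OSCA-40 and OSCA-32. Of 64 mouse genes higher with OSCA-40, those named by the rule were Ighv1-12 (log2 fold change 2.77), Saa2 (2.55), Vps33a (2.15), Bcam (2.09), H2-T24 (1.83), Pf4 (1.78), Rbm17 (1.59), Phkg2 (1.49), Tmsb4x (1.35), U2af2 (1.34), Hba-a2 (1.30) and Pecam1 (0.83). Of 76 lower with OSCA-40 they were Speer4c (fitted value -3.92, listed at 0 there), mt-Co2 (-3.07), Vcan (fitted value -2.96, listed at 0 there), Zfp991 (-2.10), Mdm2 (-2.02), Crat (-1.95), Pdpk1 (-1.70), Zdhhc9 (-1.67), Pramel5 (-1.64), Rpl36 (-1.55), mt-Nd1 (-1.14), Cd9 (-0.94) and mt-Co1 (-0.67). Mdm2, Crat, Pdpk1, Zdhhc9 and Rpl36 were listed at 1 to 3 in the OSCA-40 libraries. The erythroid list had a median of 0.23 and the platelet list of 0.52.

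The fall of mt-Co2 came with a rise of Gm28661, its identical copy on chromosome 1, which stood at 0 in both OSCA-32 libraries and at 57 and 47 with OSCA-40. Less mitochondrial RNA with OSCA-40, relative to the bulk of genes, is argued against as the source of the -3.07 of mt-Co2. The 6 mitochondrial mRNAs without a copy had a median log2 fold change of -0.14 and none below -1.14. A smaller decrease is not excluded by this. As deposited, where the median mouse gene was also lower with OSCA-40, the mitochondrial mRNAs summed to 996 and 715 with OSCA-32 and 380 and 350 with OSCA-40. Reads shared between gene and copy may account for the pattern: summed, the pair differed between the lines by 0.10 ± 0.16 (SE). A difference of mt-Nd1, which has no copy found here, stays open and was not tested further.

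A pair of canine genes changed places between the lines: ENSCAFG00000031490 was high in OSCA-32 and near absent in OSCA-40, and ENSCAFG00000030616 the reverse. The highest scaled OSCA-40 value of ENSCAFG00000031490 was 0.0602% of its lowest scaled tumour-free value. If reads are assigned to each gene apart, this argues against canine RNA that differs between the lines and only adds to an unchanged background. If the genes share reads, added RNA could also change where background reads are assigned, and this test cannot decide. That reads of one kind of RNA may be assigned to either gene cannot be told apart from a loss of the tumour-free signal by other means: the summed pair was at least 4.90 times higher in each tumour library than in any tumour-free library, and no canine sequence was used here. How much the lines differ in the RNA they add stays open. Only where reads are assigned to each gene apart would more or less of it leave in place a signal that was there without a graft.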

How the results depend on the processing

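Median-of-ratios scaling changed no count by over 1.5 times and no call of a named gene. Library totals alone made the larger canine share count as a fall of most mouse genes: 1353 genes differed for OSCA-32 against PBS, 6725 for OSCA-40, 6033 for both lines and 4638 between the lines, and r between the lines was 0.55. With no filter the counts were 2312 for OSCA-40, 1277 for both lines, 1654 between the lines and 2 for PBS against week 0, with r = 0.42, and 15.2% of the mouse genes called for OSCA-40 and 28.0% for both lines were higher; for OSCA-40 that share was 48.3% with a minimum of 5 and 49.2% with no variance trend, both chosen after seeing the data. A mean of at least 50 gave 131 for OSCA-32, 24 for PBS against week 0 and r = 0.71. Fitting only the groups compared, with fewer samples, gave 46, 320, 2 and 84 for OSCA-32, OSCA-40, PBS against week 0 and between the lines. Removing mitochondrial, haemoglobin and structural RNA genes gave 8 for PBS against week 0. Of the alternatives chosen after seeing the data, no variance trend gave 313 for OSCA-40, 204 for both lines, 5 for PBS against week 0 and 112 between the lines; mouse genes alone, scaled on themselves and with no canine calls to count, gave 28 for OSCA-32, 207 for both lines, 8 for PBS against week 0 and 108 between the lines, where the mouse calls had been 42, 242, 9 and 140; a minimum of 5 gave 8 for PBS against week 0 and r = 0.45; a pseudocount of 4 gave r = 0.52; and PBS libraries split between the lines gave r = 0.239 and 0.217. Where no construction is named, the cause was not tested.

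Leaving out 1 library gave 36 to 90 genes for OSCA-32, 268 to 551 for OSCA-40, 135 to 352 for both lines, 2 to 7 for PBS against week 0 and 69 to 166 between the lines, r from 0.40 to 0.59, 6 to 12 lists, and a canine share difference of 36.3 to 45.4 percentage points, whose exact permutation p of 0.0571 is the smallest that 35 splits allow. A lone library of a group is assumed to vary like the others. Of 112 calls of named genes over the comparisons, 38 held without each of the 8 libraries and none changed sign. Of 11 list calls, 1 held with an estimated correlation, and fry gave 19.

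With the replicate number as a block, 6 genes differed for PBS against week 0 and 144 between the lines; the other counts stayed within 1.5 times, and 23 of the named genes' calls were lost. Nothing pairs the libraries: the differences between replicates 1 and 2 correlated between groups at -0.06 to 0.01.

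Signs that turned with library totals alone, for OSCA-40 against PBS, were Ank1 -0.61, Atp6v0d2 -1.29, Clcn7 -0.89, Hbb-bs -1.13, Hist1h2bc -0.015, Hist4h4 -1.46, Icam2 -0.014, Itih4 -0.74, Notch1 -0.27, Oasl2 -1.01, Pck1 -0.84, Pecam1 -0.33, Rab11a -0.64, Saa4 -1.28, Tcirg1 -1.001, Trf -0.81, Xaf1 -0.42, mt-Cytb -0.31 and mt-Nd4 -0.17. For both lines they were Atp6v0d2 -0.75, Clcn7 -0.50, Hba-a2 -0.070, Hbb-bs -0.68, Pecam1 -0.22, Rab11a -0.39, Tcirg1 -0.46 and Trf -0.57, and between the lines Itih4 -0.082 and Pecam1 -0.21. For the ribosomal protein list and both lines, the direction of the test turned with library totals alone, from lower to higher relative to other genes, while the median was negative in both (-0.09 and -1.08); it passed in neither. With no filter Hist4h4 was -0.064 and the histone list -0.40 for OSCA-40, with week 0 as the reference Serpina1b was -0.37, and summed with their copies mt-Co1 was 0.039 and mt-Co2 0.10 between the lines. Of 89 list and comparison pairs past the threshold in no setting, 57 changed the direction of the test in at least 1. DESeq2, limma-voom and the legacy quasi-likelihood test were not run because the values are not counts, and the canine share without mitochondrial and ribosomal RNA genes was not run because canine genes are unnamed. The unknown depth leaves open how far low values are limited by few reads.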

Other observations

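The tests in this part were chosen after the results were seen. Taken alone, the 13 mitochondrially encoded mRNAs differed between the lines by -3.07 to 3.89 on the log2 scale, and summed with their copies by -1.14 to 0.10. Of the 7 with a copy, mt-Atp6, mt-Co1, mt-Co2, mt-Nd3 and mt-Nd4l came closer to 0 and mt-Nd4 stayed at -0.06, whereas mt-Co3 went from -0.25 to -0.70 ± 0.20 (SE), which did not pass. Against PBS, the summed mt-Atp6 changed by 1.59 ± 0.13 with OSCA-32 and 1.67 ± 0.13 with OSCA-40, mt-Co2 by 1.16 ± 0.16 and 1.25 ± 0.16, mt-Co1 by 1.06 ± 0.15 and 1.10 ± 0.15, and mt-Co3 by 1.37 ± 0.20 with OSCA-32, while its 0.67 ± 0.20 with OSCA-40 did not pass. From week 0 to PBS the median of the 13 genes was 1.38, and camera on the summed values gave an adjusted p of 4.47e-34 and, with an estimated correlation, adjusted p = 0.0400. Between the lines their median was -0.06 (adjusted p = 0.471).

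Sensory receptor genes were listed at levels near those of other genes. The median of 1583 olfactory, vomeronasal and trace amine receptor genes was 3 in each tumour-free library, that of protein-coding genes was 5, and that of 77 ribosomal protein genes was 9 or 10; 95.3% of protein-coding genes were at 1 or more on average there. Cellular mRNA as the main source of the typical value is argued against, since ribosomal protein genes exceeded receptor genes by at most 3.33 times in any library. Reads from DNA, or from another source spread evenly over genes, may make up much of the typical value: the receptor median was at least 0.50 of the protein-coding median in every library, where the low whole numbers with OSCA-40 make that ratio coarse. No biological explanation was tested, and DNA was not distinguished from other even sources.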
